A study of Mus musculus with 10 samples.

How the data were processed

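Hippocampal microglia of 10 male Balb/c pups, 5 control and 5 BDS, were measured at postnatal day 14. Per the labels' protocols, cells were isolated on a Percoll gradient and sorted by FACS, 2 ng of RNA was turned into cDNA, amplified by 5 rounds of PCR and hybridized to an nCounter mouse immune panel. Groups and pup numbers come from the sample titles, and per the series' design text all pups were from different litters, so p-values refer to the spread between pups.

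The deposited raw table holds counts of fluorescent barcodes per probe, not normalized, for 545 endogenous genes, 14 housekeeping genes, 8 negative control probes and 6 positive control probes; the counting software and its version are not given in the sources used here. The authors' second deposited table holds normalized counts, treated here as a score because they are scaled and rounded to whole numbers, together with group means. Per the series' design text the authors scaled to positive controls and 5 housekeeping genes, but that text names 6. In the values, the deposited scores equalled raw counts times 1 factor per lane, and among 16383 subsets of the 14 housekeeping genes only the geometric mean of Alas1, Gapdh, Oaz1, Polr1b and Tbp, without Sdha, gave that factor (SD of the log ratio 2.38e-05, next best 0.0273). The rescaled raw counts differed from the deposited scores by at most 3 units, where the largest score was 111422. The deposited percent of samples above background matched, in all genes, a limit of 23 normalized counts in each lane; per the series' design text the limit was the mean plus 2 SD of the negative probes, and the pooled raw negative probes give 22.6. That table's fold change (a ratio of the group means, per the file headers) and its p-value (headed as a t-test by the authors, not adjusted) were copied and not recomputed for the text; the p-values lie nearest to a two-sided equal-variance test on the deposited scores. The second block of that table repeats the header line, which was dropped.

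Because a scale factor from positive controls cancels once a lane is divided by its housekeeping mean, lanes were scaled by the geometric mean of all 6 named housekeeping genes. Genes were tested if raw counts exceeded the lane's own negative-control mean plus 2 SD in at least 4 of 10 lanes (40%), which kept 283 of 545; all 283 are among the authors' 309. Raw counts were fitted with edgeR 4.0.16 (quasi-likelihood F test, two-sided, housekeeping offsets, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over the 283 genes, and standard errors were taken as the log2 fold change over the square root of F. Normalized counts are raw counts divided by the lane's housekeeping mean, rescaled to the geometric mean over lanes; a log2 scale uses a pseudocount of 1. Positive log2 fold changes mean higher in BDS. The 24 gene lists (16 pathways and 8 of other cell types) were tested on log2 normalized counts with limma 3.58.1, using camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, for lists with at least 5 present genes; members were also adjusted over the list alone. Camera compares a list with the other genes, while fry asks whether its genes move one way on balance. Single values per lane were compared by exact two-sided permutation tests over all 252 assignments. DESeq2 1.42.0 served as a second tool.

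The design, the gene lists, the rule for named genes and all alternatives but 4 were fixed before the data were examined. The rule named the 12 genes with the smallest edgeR p in each direction, up to 3 present members of each list with the smallest p, the 6 housekeeping genes and 14 fixed genes. Il10rb, Il10ra, Zbtb7b, C1qb, Cd164, Tlr9, Npc1, Atm, Hprt, Rpl19 and Gusb were named after their values were seen. The alternatives covered other scalings (TMM, median-of-ratios, positive controls alone, all 14 housekeeping genes, each of the 6 left out), other filters, background subtraction, the authors' scores, other tools, sample weights, lane depth as a covariate, and each pup left out in turn; the closing section gives their effect. Added after seeing the data were fits without the lowest lanes (control 52 and 69), without these and BDS 17, on the authors' 309 genes, and the count at an unadjusted p under 0.05 for every setting but the planned fit.

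Endogenous counts per lane ran from 76237 to 968930. Counts follow amplification of cDNA and carry no molecular identifiers, so they are not independent molecules. No pair of lanes was alike to within sampling noise, with a chi-square per degree of freedom over genes of 22.8 or more. The edgeR step was tested on simulated data made from these lanes (10 runs of 545 genes, 200 of them changed): it called 30.8% of genes changed 1.5-fold, 78.1% of those changed 2-fold and 99.8% of those changed 4-fold, and 4.73% of unchanged genes had a p under 0.05. Every simulated gene followed lane depth in proportion and varied independently of the others. In the real lanes, within-group slopes of log2 raw count on log2 lane depth ran from -0.23 to 1.63, where 1 is proportional. The simulated rates therefore need not hold for these data. Of 559 gene probes, 547 matched a RefSeq accession of the GRCm38.p6 gene table, and 13 panel symbols differ from the current ones. Results of single genes that needed items withheld from the text are not reported here, and these genes were left out of the outlier search and the per-gene table of alternatives, but not of the tests. The build behind the probes is not given in the sources used here, so no coordinates are given. Housekeeping and control probes were not tested as genes of interest, and no column of the tables was left out for lack of a sample.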

Results

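Microglia, the resident macrophages of brain tissue, were sorted from the hippocampus of male Balb/c mouse pups at postnatal day 14. They were profiled on the nCounter mouse immune panel, which counts fluorescent barcodes bound to target molecules, here amplified cDNA, and needs no sequencing. The 5 control pups were numbered 1, 18, 40, 52 and 69 in the labels, and the 5 pups given brief daily separation (BDS) were numbered 11, 17, 24, 38 and 59. BDS took pups from the dam for 15 min a day, a schedule the labels give as postnatal days 1 to 21, so pups collected at day 14 were still within it. All 10 pups came from different litters, and each was read in 1 lane. The panel held 545 endogenous genes, of which 283 exceeded the negative-control limit in at least 4 of the 10 lanes and were tested. Endogenous counts per lane ranged from 76237 in control 52 to 968930 in BDS 17. The mean was 371619 ± 281958 (SD, n = 5) in control lanes and 716937 ± 245521 (SD, n = 5) in BDS lanes.

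Csf1r, the receptor for the growth factors that keep microglia alive, took 9.92% ± 3.20 of endogenous counts in control lanes (SD, n = 5) and 11.0% ± 1.17 in BDS lanes (n = 5). In control and BDS lanes, the tetraspanin Cd81 took 10.7% ± 2.30 and 7.70% ± 1.35, the integrin Itgam 8.71% ± 2.19 and 5.77% ± 0.804, and the lysosomal protease Ctss 4.72% ± 0.935 and 6.43% ± 0.760. The sialomucin Cd164 took 4.17% ± 1.08 and 5.80% ± 0.626, and the complement gene C1qb 3.60% ± 0.960 and 3.46% ± 0.319. With differences in both directions, these 6 genes together made up 41.8% ± 3.21 of counts in control lanes and 40.2% ± 2.27 in BDS lanes (exact two-sided permutation p = 0.357, n = 5 each). All 13 microglia identity genes on the panel were present, and their summed share was 33.9% in control lanes and 33.0% in BDS lanes.

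The first comparison asked which immune genes of hippocampal microglia differed between BDS and control pups. In BDS lanes C1qa, a chain of the C1q molecule that starts the classical complement pathway, was higher. It stood at 15823 ± 3865 normalized counts (SD, n = 5) against 9356 ± 1876 in control lanes (n = 5), a log2 fold change of 0.76 ± 0.20 (SE; edgeR adjusted p = 0.0642). Csf1, a growth factor that binds Csf1r, was higher too, at 187 ± 39.6 against 97.9 ± 25.6, a log2 fold change of 0.91 ± 0.24 (edgeR adjusted p = 0.0642). Lower values were found for Itgam, the alpha chain of complement receptor 3, at 25334 ± 2802 against 37418 ± 9352, a log2 fold change of -0.56 ± 0.18 (edgeR adjusted p = 0.0964). Cx3cr1, the microglial fractalkine receptor, was lower as well, at 7786 ± 993 against 12088 ± 4829, with -0.63 ± 0.23 (edgeR adjusted p = 0.126). That value was -0.38 without control 52 and -0.13 with lane depth as a covariate, where C1qa was at 0.47, Csf1 at 0.65 and Itgam at -0.65. None of the 283 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the smallest value was 0.0642.

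The 12 genes with the smallest p among those higher in BDS included Jak3, Psmb7, C1qa, Fyn, Bcap31, Lcp2, Csf1, Tbk1, Casp8, Itgb1 and Ncf4. The log2 fold changes of these named genes lay between 0.65 ± 0.19 for the integrin beta chain Itgb1 and 1.07 ± 0.27 for Jak3 (SE, n = 5 per group), with edgeR adjusted p from 0.0642 to 0.0706. Jak3, a kinase of cytokine receptors, stood at 859 ± 376 normalized counts in BDS lanes and 405 ± 94.1 in control lanes. Casp8, the initiator protease of death receptor signalling, stood at 1477 ± 387 against 834 ± 192, and Tbk1, a kinase of innate immune sensing, at 807 ± 134 against 504 ± 77.5. Each of the 12 exceeded the control mean in 5 of 5 BDS lanes, and all 12 were higher under each of the 10 other scalings tried. They were chosen by their p in these same lanes, so this is no separate support. With lane depth as a covariate all 12 kept the direction, and their median log2 fold change was 0.65 in place of 0.87, with Jak3 at 0.66 and Itgb1 at 0.43.

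Among genes lower in BDS, the 12 with the smallest p included Fcgr3, Tnfrsf13b, Csf3r, Itgam, Tap1, Tnfrsf17, Cx3cr1, Src, Cd40lg, Cd81 and Nfil3. Fcgr3, a low-affinity IgG receptor, was at 76.0 ± 18.3 normalized counts in BDS lanes and 343 ± 354 in control lanes (SD, n = 5 each), a log2 fold change of -2.12 ± 0.53 (SE; edgeR adjusted p = 0.0642). Tnfrsf13b, a receptor best known from B cells, was at 21.7 ± 10.1 against 106 ± 120, with -2.16 ± 0.65 (edgeR adjusted p = 0.0858). Without control 52, where both stood highest, the log2 fold change of Fcgr3 was -1.30 and that of Tnfrsf13b -1.26. The peptide transporter gene Tap1 and the T cell ligand gene Cd40lg exceeded the negative-control limit in only 4 of 10 lanes each, so their lower values lie close to background. Csf3r, the receptor of granulocyte colony-stimulating factor, had a log2 fold change of -0.77 ± 0.24 (edgeR adjusted p = 0.0890) and Cd81 one of -0.45 ± 0.17 (edgeR adjusted p = 0.129). All 12 lay below the control mean in 5 of 5 BDS lanes, but they were chosen by their p in these same lanes. Control 52 also raised the control mean of several. Fcgr3 stood at 949 in control 52 and at 80.5 in control 40, the latter below BDS 11 at 98.0. The 12 genes stayed lower under 9 of the 10 other scalings. Scaling to the positive controls alone put 281 of the 283 genes higher, these included but for 2, so that turn is not particular to them. With lane depth as a covariate the log2 fold change of Fcgr3 was -0.49, that of Tnfrsf13b -0.15, that of Tnfrsf17 -0.16, that of Nfil3 -0.20, that of Csf3r -0.37 and that of Cx3cr1 -0.13. Those of Itgam (-0.65), Src (-0.47) and Cd81 (-0.39) kept most of their size. Raw counts of Fcgr3 ranged from 81 to 204 over the 10 lanes, while those of C1qa ranged from 1461 to 41092.

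**Figure D1:**
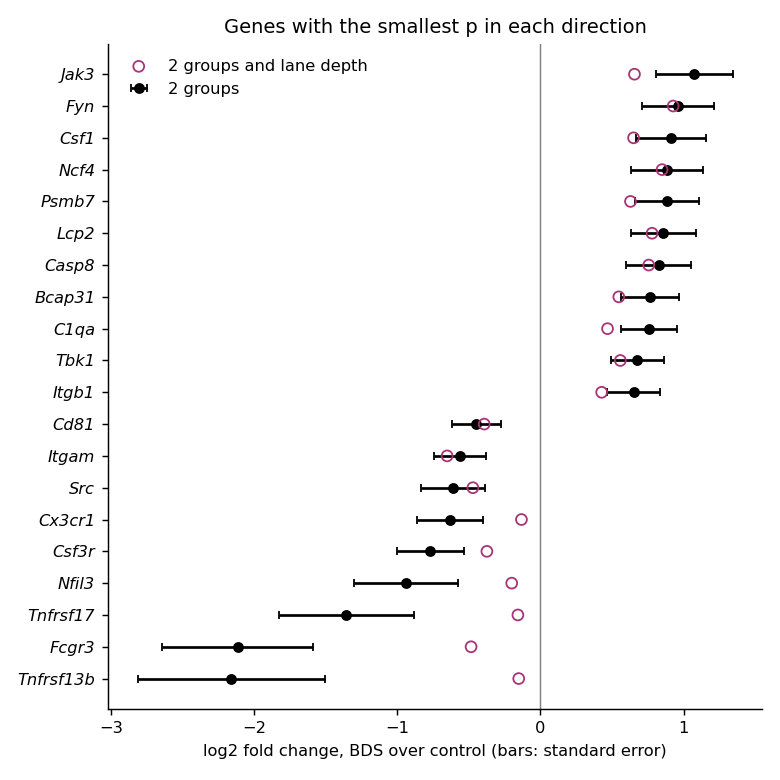
Log2 fold change of BDS over control for genes with the smallest p in each direction, with filled points and bars for the fit of the 2 groups (estimate and standard error, n = 5 per group) and open circles for the fit that also holds lane depth. The open circle of Tnfrsf13b lies at -0.15 and its filled point at -2.16, while those of Fyn lie at 0.93 and 0.96.

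**Figure D2:**
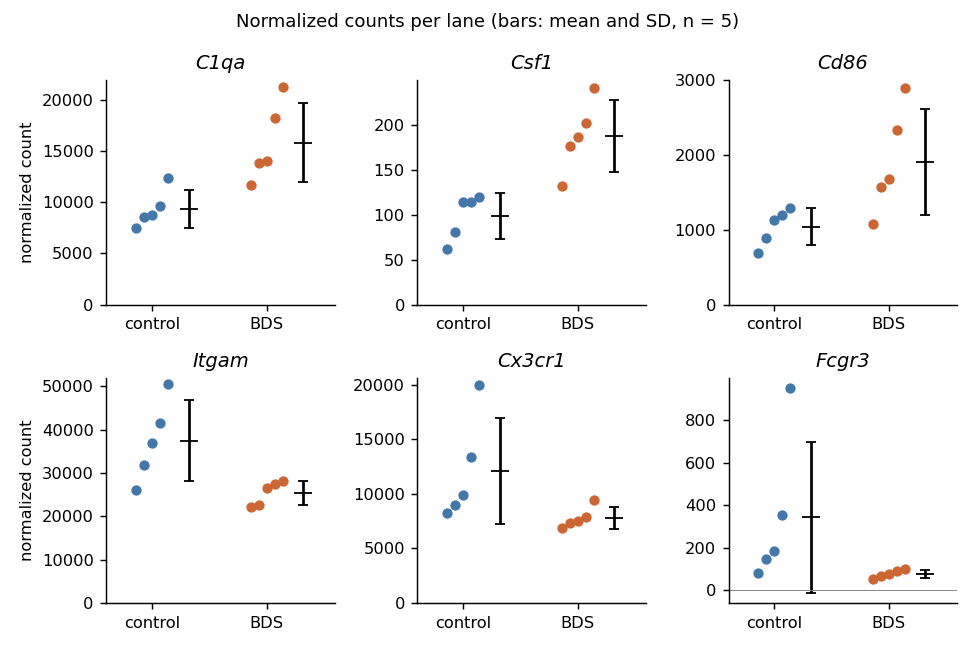
Normalized counts of 6 genes in each lane, with control lanes in blue and BDS lanes in orange (n = 5 each) and bars for the group mean and SD; every vertical axis is linear. C1qa, Csf1 and Cd86 were higher in BDS lanes and Itgam, Cx3cr1 and Fcgr3 lower, and the control values of Fcgr3 spread from 80.5 to 949.

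At an unadjusted p under 0.05, 80 of the 283 genes differed by edgeR, 55 higher and 25 lower in BDS, where 14.2 would pass by chance. The count was 45 without BDS 17, 36 with lane depth as a covariate (26 higher, 10 lower) and 139 with no filter on low counts (53 higher, 86 lower). At a looser bound, 23 genes (19 higher, 4 lower) passed an adjusted p of 0.10. DESeq2 with the same housekeeping scaling called 26 genes at an adjusted p under 0.05 (20 higher, 6 lower) and 30 with its own scaling (14 higher, 16 lower). Limma called 0 at that bound without sample weights and 85 with them, and leaving out control 40 or BDS 11 gave 48 and 19 genes by edgeR at an adjusted p under 0.05. These were the deepest control lane and the shallowest BDS lane. Leaving out either widened the gap in housekeeping signal, from 1.23 to 1.61 and 1.46 on the log2 scale. Without control 18 that gap was 1.42, with 0 genes. The 55 to 25 split depended on scaling: it was 36 to 39 with TMM, 33 to 40 with median-of-ratios factors, and 128 to 0 with positive controls alone. With 1 housekeeping gene left out it was 25 to 49 without Sdha, 43 to 33 without Oaz1, 76 to 12 without Polr1b and 64 to 17 without Gapdh. In 13 genes (4.59%) the values of both groups did not overlap, 10 higher and 3 lower in BDS, a share that chance would put at 0.794%. The 13 were Bcap31, Casp2, Cd83, Chuk, Csf1, Cxcr6, Lcp2, Ncf4, Tbk1 and Zbtb7b on the higher side and Cd40lg, Il10ra and Tap1 on the lower, of which Cd40lg and Tap1 were above the limit in 4 lanes only.

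Gene lists fixed in advance were then compared, 17 of the 24 having the 5 present members needed for a test. No list passed limma's camera at an adjusted p of 0.05 (smallest adjusted p = 0.737; 0 lists at an unadjusted p under 0.05). With an estimated correlation camera called none either (adjusted p = 0.966 throughout), and fry gave 0 adjusted and 2 unadjusted lists. Fry's mixed test, which lets members of a list move both ways, gave 0 adjusted and 8 unadjusted lists (smallest fry mixed adjusted p = 0.0928). Over all 283 genes, 0 members of any list passed edgeR's adjusted p of 0.05, so the counts that follow are adjusted over the list alone. With no filter on low counts camera called 4 lists, toll-like receptor signalling, JAK-STAT signalling and T cells (adjusted p = 0.0109 each) and the interferon response (adjusted p = 0.0395), T cells lower and the others higher. That setting adds the 262 genes above the limit in fewer than 4 lanes, which are among those the lists called higher were compared with. Negative controls averaged 10 and 10.03 raw counts in control and BDS lanes. Scaled background is therefore lower in BDS lanes, which were deeper on average. Only 5 of 26 T cell genes on the panel were present, so most of that list lay near background. Median log2 fold changes of lists are read against that of all 283 genes, which was 0.09 with the 6 housekeeping genes, -0.04 with TMM, -0.09 without Sdha and 1.35 with positive controls alone, a scaling that put 281 of 283 genes higher and so turned nearly every negative value. A turn of sign under another scaling thus need not be a change relative to the panel. BDS lanes were also the deeper lanes on average, by 1.23 on the log2 scale of housekeeping signal, and this held beside every list below.

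Microglia identity genes had values on both sides of 0. Of the 13 members present, adjusted over the list alone 0 passed. At an unadjusted edgeR p under 0.05 Ctss (log2 fold change 0.48 ± 0.18) and the transcription factor Ikzf1 (0.48 ± 0.18) were higher and Itgam, Cx3cr1 and Tgfbr2 (-0.35 ± 0.15) were lower. The list median was 0.21 (camera adjusted p = 0.936). Csf1r was at 0.17 ± 0.22, a sign that turned to -0.02 without Sdha in the scaling. The phagocytic receptor Trem2 was at 0.28 ± 0.18, and the microglial transcription factor Irf8 at 0.50 ± 0.27 (SE, n = 5 per group). Ptprc, the pan-leukocyte antigen CD45, was at 0.83 ± 0.26 (edgeR adjusted p = 0.0904). Fitted with lane depth, Ctss was at 0.25, Ptprc at 0.47, Csf1r at 0.45 and Cx3cr1 at -0.13. TGF-beta signalling genes, which include the cytokine that maintains microglial identity, had 8 present members and 0 passing adjusted over the list alone. Tgfb1 was at 0.21 ± 0.18, its receptor chains Tgfbr1 at 0.40 ± 0.22 and Tgfbr2 at -0.35 ± 0.15. The list median was -0.09 and turned positive without Polr1b and with positive controls alone (camera adjusted p = 0.789).

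Complement genes split in opposite directions. Of 9 present among the 30 on the panel, 2 passed edgeR adjusted over the list alone: C1qa rose and the complement receptor chain Itgam fell, by 0.56 on the log2 scale. C1qb, the partner chain of C1qa, was at -0.03 ± 0.20, C2 was at 0.52 ± 0.41, and C3 exceeded the negative-control limit in 1 lane and was not tested. The list median of -0.07 changed sign without Gapdh, without Polr1b and with positive controls alone (camera adjusted p = 0.789). Among 13 present genes of Fc receptors, scavenging and phagocytosis, 3 passed adjusted over the list alone: Ncf4, a subunit of the phagocyte oxidase, rose (0.89 ± 0.25), Itgam fell and Fcgr3 was lower. The high-affinity IgG receptor Fcgr1 was at 0.50 ± 0.21 (edgeR adjusted p = 0.149). The fit with lane depth put Fcgr1 at 0.16, Fcgr3 at -0.49 and C2 at -0.10. The phagocytosis list median was 0.09, turning negative with TMM, with median-of-ratios factors and without Sdha (camera adjusted p = 0.936).

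Of 9 inflammatory cytokine genes present among 19 on the panel, Csf1 alone passed adjusted over the list alone and rose. Il1a was at -0.39 ± 0.19, Il1b at 0.47 ± 0.26 and Tnf at -0.48 ± 0.31 (SE, n = 5 per group), and Il6 exceeded the limit in 1 lane and was not tested. The list median was -0.14, with the opposite sign for positive controls alone (camera adjusted p = 0.789). Chemokines had the smallest camera p of the 17 lists, 0.0600 unadjusted and 0.737 adjusted. They had 7 of 25 panel genes present, a median of -0.30 (positive with positive controls alone) and 0 members passing adjusted over the list alone. The macrophage chemokines Ccl3 and Ccl4 were at -0.76 ± 0.40 and -0.61 ± 0.29, Ccl24 at -0.74 ± 0.36, and the interferon-induced Cxcl10 at 1.09 ± 0.46. Of 6 present chemokine receptors 3 passed adjusted over the list alone: Cxcr6 (0.85 ± 0.28) and Ccr2 (0.59 ± 0.23) rose and Cx3cr1 was lower. The list median was 0.56 (camera adjusted p = 0.789). Holding lane depth, Cx3cr1 was at -0.13, Cxcr6 at 0.47, Ccl24 at -0.21 and Il1a at -0.18, and without BDS 17 Cxcl10 was at 0.71. NF-kB pathway genes gave 0 of 16 adjusted over the list alone. The kinase subunits Chuk and Ikbkg were at 0.68 ± 0.21 and 0.58 ± 0.25. The median was 0.15 and turned negative without Sdha (camera adjusted p = 0.936).

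Over all 283 genes 158 were higher and 125 lower, a tally that was 134 to 149 with TMM and 131 to 152 without Sdha, against which the lists of innate sensing and cytokine signalling are read. Toll-like receptor signalling had 15 of 19 present members higher, a median of 0.30 and the second smallest camera p (0.0867, adjusted p = 0.737; fry unadjusted p = 0.0285, adjusted p = 0.359). Adjusted over the list alone 1 member, Tbk1, rose. The kinase gene Irak4 was at 0.58 ± 0.20 and Tlr1 at 0.49 ± 0.20, or 0.30 and 0.33 in the fit with lane depth. Of the interferon response, 16 of 22 were higher and 0 passed adjusted over the list alone, with the RNA sensor Ifih1 at 0.67 ± 0.28 and a median of 0.26 (camera adjusted p = 0.789). Of 24 genes of cytokine receptor JAK-STAT signalling, 15 of them higher, 4 passed adjusted over the list alone, 3 higher and 1 lower. Among them Jak3 and Il10rb (0.81 ± 0.26), a chain of the interleukin-10 receptor, rose and Csf3r was lower. The median was 0.20 (camera adjusted p = 0.789). Of 10 apoptosis genes 3 passed adjusted over the list alone and rose, Casp8, Casp2 (0.82 ± 0.24) and Bcap31 (0.77 ± 0.20). The median was 0.41 (camera adjusted p = 0.789). Immediate early and stimulus response genes gave 0 of 8 adjusted over the list alone, with the activation marker Cd83 at 0.47 ± 0.17. The median was -0.15, and it was positive with positive controls alone (camera adjusted p = 0.789).

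Antigen presentation genes included Cd86, a co-stimulatory ligand for T cells, at 1910 ± 708 normalized counts in BDS lanes against 1038 ± 246 in control lanes (SD, n = 5 each). Its log2 fold change was 0.88 ± 0.26 (edgeR adjusted p = 0.0791 over all genes). Adjusted over the list alone it was the 1 of 8 MHC class II and co-stimulation genes to pass, and it rose. The invariant chain Cd74 was at 1.098 ± 0.51, but at 0.37 without BDS 17. Icosl was at 0.51 ± 0.23 (0.25 in the fit with lane depth), with a list median of 0.30 (camera adjusted p = 0.789; fry unadjusted p = 0.0485, adjusted p = 0.359). Of 10 MHC class I presentation genes 2 passed adjusted over the list alone, the proteasome subunit Psmb7, which rose (0.89 ± 0.23), and Tap1, whose lower value lies at background in most BDS lanes. The proteasome gene Psmd7 was at -0.88 ± 0.42, but at -0.35 without control 52 and at 0.10 in the fit with lane depth. That list's median was 0.13 (negative without Sdha), its mean relative to other genes -0.14 and its camera direction down (adjusted p = 0.936). Of the 4 autophagy and ubiquitin genes present, too few for a list test, Atg16l1 (0.51 ± 0.18), a core autophagy gene, and Ctss passed adjusted over the list alone and rose. Over all genes their edgeR adjusted p was 0.126 and 0.132, and the fit with lane depth put them at 0.35 and 0.25. Cul9 was at 0.06 ± 0.24, a sign that turned with TMM, median-of-ratios factors, without Sdha and with lane depth as a covariate (-0.22).

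Markers of other cell types were mostly near background. T cell genes were present for 5 of 26 on the panel, with Cd27 at 0.69 ± 0.27 and Tcf7 at 0.33 ± 0.30. Adjusted over the list alone 0 passed, and the median was -0.01, with its sign turning under 5 of the 10 other scalings (camera adjusted p = 0.936). Of 14 B cell genes on the panel 5 were present, and Tnfrsf13b and Tnfrsf17, the receptors named above, passed adjusted over the list alone and were lower, but only by -0.15 and -0.16 in the fit with lane depth. The B cell adaptor Blnk was at 0.40 ± 0.20 (list median -0.14, positive with positive controls alone; camera adjusted p = 0.789). NK cell genes were present for 3 of 17, with 0 passing adjusted over the list alone and Prf1, Klrk1 and Klrc2 at 0.33 ± 0.35, -0.06 ± 0.24 and -0.25 ± 0.34 (list median -0.06, positive without Gapdh, without Polr1b and with positive controls alone). Of 4 present monocyte and granulocyte genes, 2 passed adjusted over the list alone: Ccr2 rose and Csf3r was lower, and the tetraspanin Cd9 was at -0.20 ± 0.23 (list median -0.13, positive with positive controls alone). Perivascular and border macrophage genes were present for 2 of 9, Ccl24 and Cd74, with 0 passing adjusted over the list alone and a median of 0.18 that was negative without Sdha, and 0 of 3 mast cell and basophil genes were present. Of 4 present endothelial and platelet genes 0 passed adjusted over the list alone, with the junction genes Cdh5 at 0.97 ± 0.37 and Pecam1 at -0.56 ± 0.24, and Cd34 at -0.42 ± 0.24 (list median 0.04, negative with TMM, with median-of-ratios factors, without Oaz1 and without Sdha). Neuronal and glial genes were present for 2 of 3, 0 passing adjusted over the list alone (list median -0.02, positive under 5 of the 10 other scalings), with the myelin gene Mbp at -0.15 ± 0.28 and Ncam1 at 0.10 ± 0.39, signs that turned under 1 or more scalings, as did that of Klrk1. Klrc2 and Ncam1 exceeded the limit in only 4 of 10 lanes each, so their values are near background. Among these markers the fit with lane depth gave Cd27 0.40, Tcf7 -0.12, Prf1 -0.26, Klrc2 0.18, Cd9 0.18, Cdh5 0.40, Pecam1 -0.85, Mbp 0.04 and Ncam1 0.58. The shares of endogenous counts taken by all panel members of these lists, in control and BDS lanes, were 0.438% and 0.403% for T cells, 0.425% and 0.461% for B cells, and 0.0606% and 0.0411% for NK cells. They were 0.862% and 0.590% for monocytes and granulocytes, 0.0421% and 0.0256% for perivascular and border macrophages, 0.00596% and 0.00319% for mast cells and basophils, 0.320% and 0.245% for endothelium and platelets, and 0.0347% and 0.0288% for neurons and glia. These sums include probes at background, which was not subtracted. Negative controls averaged 10 and 10.03 raw counts in control and BDS lanes, so background takes a smaller share of the deeper BDS lanes. A lower share in BDS lanes therefore does not show fewer such cells.

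The second comparison asked whether lanes of both groups gave equal signal before normalization and equal detection. The geometric mean of the 6 housekeeping genes was 497 ± 377 raw counts in control lanes and 931 ± 301 in BDS lanes (SD, n = 5 each), a difference of 1.23 on the log2 scale or 2.35-fold (exact two-sided permutation p = 0.0873; the smallest p that 5 against 5 allows is 0.00794). It ran from 113 in control 52 to 1254 in BDS 17, and control 40, at 1060, was the deepest control lane. Genes above the negative-control limit numbered 252.2 ± 32.7 in control lanes and 303.2 ± 45.7 in BDS lanes (exact permutation p = 0.0635). This difference passed at a limit of mean plus 3 SD (exact permutation p = 0.0397), without control 40 (exact p = 0.0159) and without BDS 11 (exact p = 0.0317), and that of housekeeping signal passed without control 40 (exact p = 0.0238). The spiked-in positive controls went the other way, with a geometric mean of 1697 ± 174 in control lanes and 1361 ± 172 in BDS lanes (-0.32 on the log2 scale; exact permutation p = 0.0238). The negative controls averaged 10 ± 2.80 and 10.03 ± 1.24 counts.

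**Figure D3:**
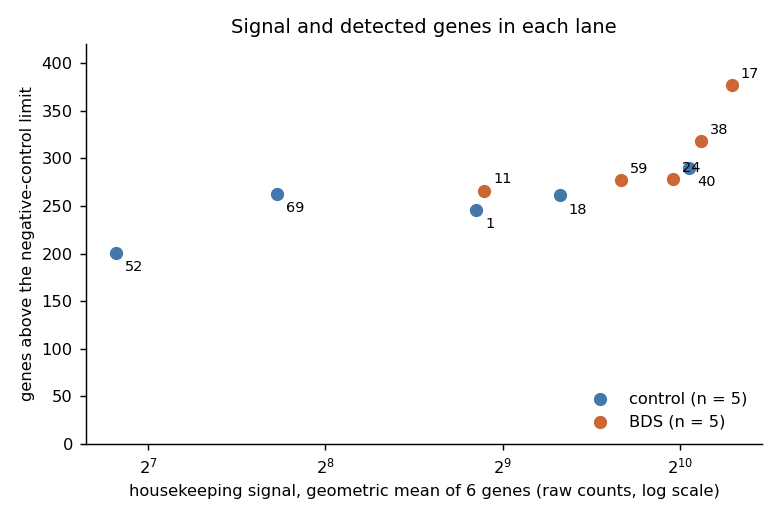
Housekeeping signal of each lane (horizontal axis, geometric mean of 6 genes in raw counts, log scale) against the number of endogenous genes above its negative-control limit (vertical axis), with control lanes in blue, BDS lanes in orange and pup numbers beside the points (n = 5 each). Control 52 lies lowest at 113 counts and 201 genes, BDS 17 highest at 1254 counts and 377 genes.

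The housekeeping genes themselves were not level between groups once scaled to their joint mean. Sdha, a subunit of mitochondrial complex II, was 0.93 lower in BDS on the log2 scale (-0.93; exact permutation p = 0.0159, n = 5 each) and Polr1b, a subunit of RNA polymerase I, was higher by 0.51 (exact permutation p = 0.0397). Gapdh (0.32; exact p = 0.103), Tbp (0.28; exact p = 0.175), Oaz1 (-0.26; exact p = 0.167) and Alas1 (0.08; exact p = 0.484) did not pass. These 6 are part of 14 housekeeping genes tested alike, and the p-values are unadjusted. Among the other 8, the lowest were Hprt at -0.92 (exact permutation p = 0.0159) and Rpl19 at -1.29 (exact permutation p = 0.0873). The highest was Gusb at 0.65 (exact permutation p = 0.111). Each sign is relative to the mean of the 6. Within-group slopes of log2 raw count on log2 lane depth, where 1 is proportional, were 0.63 for Sdha, 0.43 for Hprt and -0.04 for Rpl19. Those of Polr1b (raw counts 6 to 148) and Gusb were 1.23 and 0.88. The lower values of Sdha, Hprt and Rpl19 and the higher one of Polr1b thus cannot be told apart from lane depth. The median log2 normalized count over the 283 genes was 8.17 ± 0.15 in control lanes and 8.43 ± 0.18 in BDS lanes (SD, n = 5 each), a panel-wide shift of 0.26 (exact permutation p = 0.0556). That shift was 0.08 without Sdha (exact permutation p = 0.468), 0.14 with TMM (exact permutation p = 0.0159), 1.81 with positive controls alone (exact permutation p = 0.0476) and -0.39 over all 545 genes (exact permutation p = 0.230).

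**Figure D4:**
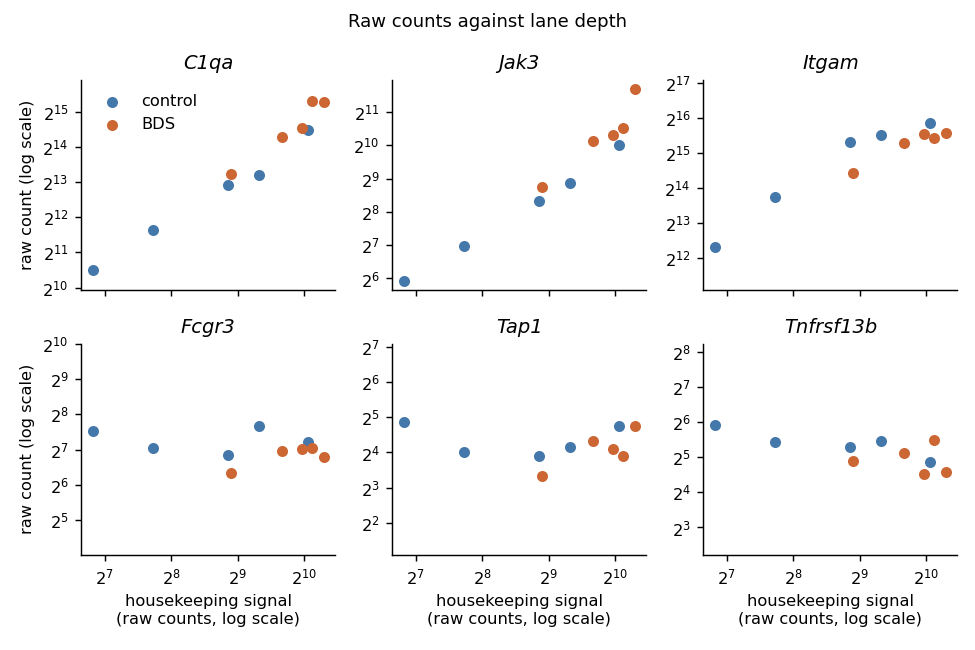
Raw counts of 6 genes against the housekeeping signal of the lane, both on log scales (vertical ranges differ between panels), with control lanes in blue and BDS lanes in orange (n = 5 each). Counts of C1qa, Jak3 and Itgam follow the signal of the lane, with C1qa from 1461 to 41092, whereas those of Fcgr3 (81 to 204), Tap1 (10 to 29) and Tnfrsf13b (23 to 61) do not.

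The third comparison set the authors' deposited table beside the edgeR fit. The authors' deposited table, whose p-values are unadjusted and not from an exact test, gave Tlr9, a sensor of unmethylated DNA, a fold of 0.66 (p = 0.0012), Csf1 one of 1.69 (p = 0.0042), Tgfbr2 one of 0.69 (p = 0.0046), Itgam one of 0.60 (p = 0.0080) and C1qa one of 1.49 (p = 0.0122). The authors' deposited table gave Fcgr3 a fold of 0.19 with p = 0.136, against an edgeR log2 fold change of -2.12. Of the 309 genes the authors' deposited table groups as present, 54 had a p under 0.05, 24 higher and 30 lower in BDS, and 0 passed after Benjamini-Hochberg adjustment (smallest adjusted value 0.232). Of those 54, 53 were among the genes tested by edgeR, all 53 with the same direction, and 35 also had an edgeR p under 0.05. Both used the same raw counts, so a shared direction is no independent support. The deposited scores were scaled without Sdha, and without it the edgeR split was 25 higher to 49 lower.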

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

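The 3 tests that split the lanes at random, the depth split and the slope of the 12 higher genes were set before their results were seen, and the covariate test, the left-out pups and both slope tests of lower genes were chosen after the result was seen. Among 160 sets of 5 values, 9 held a single lane far from the other 4, where chance alone would pick about 1 in 20, or 8. Of the 9, 4 came from control 52, the lane of lowest signal: Tap1 at 148 normalized counts (other control lanes 14.7 to 43.5), Il1a at 3427 (2018 to 2409), Cd74 at 45.9 (16.3 to 21.7) and Klrc2 at 40.8 (13.5 to 19.0). BDS 17, the lane of highest signal, held Jak3 at 1505 (other BDS lanes 518 to 789) and Cd74 at 119 (21.3 to 47.2). Others were Ctss at 35959 in BDS 38 (25758 to 27302), Cd83 at 661 in BDS 59 (499 to 523) and Il6 at 14.5 in BDS 11 (9.19 to 9.32). Cd74 and Klrc2 in control 52 and Il6 in BDS 11 were below the negative-control limit of their lane, so these 3 are scaled background.

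The first pattern is the number of genes, 80, at an unadjusted edgeR p under 0.05. Of 100 splits of the lanes, counting the real one, 2 gave as many, and the highest other split gave 115. A random split thus seldom gave this count. That highest split, though, was the 5 deepest lanes against the 5 shallowest, so lane depth could be part of the cause. It was also the real split with only control 40 and BDS 11 exchanged, and 68 of its 115 genes were among the 80. An effect of BDS could fill it too, so this split cannot tell depth from BDS. Chance is not excluded, because it may have placed deeper lanes in BDS (exact permutation p = 0.0873 for the housekeeping signal). Depth could also be the whole cause: with depth as a covariate the count was 36, of which 23 were among the 80, and 12 of 100 splits fitted alike, the real one included, gave as many, and the highest other gave 95. A single pup is not the source, since the lowest count with 1 pup left out was 45. An effect of BDS itself, as a hypothesis, remains open and untested, because BDS lanes were deeper on average and depth was not set apart from group by the design.

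The second pattern is the set of 12 genes lower in BDS. For the 8 of low raw count, raw signal rose with depth within groups with a median slope of only 0.298 ± 0.140 (SE), where 1 would be proportional, and their median log2 fold change went from -1.16 to -0.30 with depth as a covariate. Division by the housekeeping mean may by itself make most of these 8 genes lower in the deeper BDS lanes. Examples are Fcgr3 (slope 0.041), Tap1 (0.080) and Tnfrsf17 (0.18). This is less clear for Src (slope 0.88, from -0.61 to -0.47) and Cd40lg (0.85, from -0.96 to -0.80), which follow depth nearly in proportion with both groups pooled. For the 4 of high count, Csf3r, Itgam, Cx3cr1 and Cd81, the slope was 0.824 ± 0.101 and the median went from -0.60 to -0.38 with depth held, but Itgam (slope 1.08, to -0.65) and Cd81 (slope 0.96, to -0.39) follow depth nearly in proportion too. For Cx3cr1 (slope 0.67, to -0.13) and Csf3r (0.69, to -0.37) the same cause cannot be told apart from a lower level in BDS, because their slopes lie between the bounds of 0.5 and 0.8 set for either reading.

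The third pattern is the set of 12 genes higher in BDS, whose raw counts rose with depth with a median slope of 1.18 ± 0.0330 (over genes, as above), against 0.985 over all 283 genes. Signal that rises more steeply than depth may account for part of their higher values, and their median log2 fold change went from 0.87 to 0.65 with depth as a covariate. For the 12 as a set, a higher level in BDS, as a hypothesis, cannot be told apart from such signal. The median slope lies between the bounds set in advance for either reading. Members differed, however. With both groups pooled, Fyn (slope 0.998, from 0.96 to 0.93) and Ncf4 (1.002, from 0.89 to 0.85) followed depth nearly in proportion. So did Lcp2 (1.04, from 0.86 to 0.78), Casp8 (1.04, from 0.83 to 0.76) and Tbk1 (1.096, from 0.68 to 0.56). Within BDS lanes, though, the normalized counts of these genes were higher in BDS 17, the deepest, than in BDS 11, the shallowest. Fyn went from 131 in BDS 11 to 317 in BDS 17, Lcp2 from 278 to 598 and Casp8 from 1023 to 1997. Ncf4 went from 310 to 477 and Tbk1 from 755 to 928. How much of their higher values a steeper rise accounts for thus cannot be told. Jak3 rose more steeply (slope 1.32, from 1.07 to 0.66).

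The splits say nothing about chance for genes at an adjusted p under 0.05 or for gene lists, because the real value was 0 in both and every split had to give at least as many. This was so in 100 of 100 splits for genes, where the highest other was 82, and in 100 of 100 for lists, where the highest other was 2.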

How the results depend on the processing

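The fits without the lowest lanes, without these and BDS 17, on the genes the authors group as present, and the count at an unadjusted p under 0.05 in settings other than the planned fit were chosen after the result was seen. No paired analysis was possible because pup numbers are not shared between groups. The count of 0 genes at an adjusted p under 0.05 became 14 with positive controls alone, 12 without Gapdh, 15 without Polr1b, 10 among genes above the limit in all 10 lanes, 1 after background subtraction with limma, 26 by DESeq2 with housekeeping factors (20 higher, 6 lower), 30 with its own (14 higher, 16 lower), and 85 by limma with sample weights. It became 23 at an adjusted p under 0.10 and 80 at an unadjusted p under 0.05, which follows from the threshold, and for the rest the cause was not tested. Over the 10 left-out pups it ran from 0 to 48, with 48 without control 40 and 19 without BDS 11, 18 of them shared. Control 40 was the deepest control lane and BDS 11 the shallowest BDS lane, so leaving out either widened the depth gap between groups. The count of 80 at an unadjusted p became 128 with positive controls alone, 139 with no filter (53 higher, 86 lower), 122 with sample weights and 36 with depth as a covariate, and ran from 45 (without BDS 17) to 108 (without control 40). It was 87 without control 52 and 69, 65 without these and BDS 17, and 87 on the genes the authors group as present, with 0 adjusted in each. Lists at an adjusted p under 0.05 went from 0 to 4 with no filter (toll-like receptor signalling 0.41, cytokine receptor JAK-STAT signalling 0.47 and T cells -0.43, camera adjusted p = 0.0109 each, and interferon response 0.32, camera adjusted p = 0.0395) and stayed at 0 for every pup left out. With no filter the lists were tested with the 262 genes above the limit in fewer than 4 lanes added.

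The panel-wide shift of 0.26 became 0.14 with TMM, 0.13 with median-of-ratios factors, 1.81 with positive controls alone, 0.40 with all 14 housekeeping genes, 0.28 without Alas1, 0.32 without Gapdh, 0.36 without Polr1b, 0.32 without Tbp and 0.34 after background subtraction, each with an exact p from 0.0159 to 0.0476, and turned to -0.39 with no filter (exact p = 0.230). It did not pass at 0.077 on the authors' normalized values (exact p = 0.468), 0.076 without Sdha (exact p = 0.468), 0.13 for genes above the limit in all 10 lanes (exact p = 0.119) or 0.21 without Oaz1 (exact p = 0.0794). It ran from 0.20 to 0.32 over left-out pups, passing without control 69 (0.31) and without BDS 11 (0.32; exact p = 0.0238 each), the housekeeping signal from 0.80 to 1.61 and the difference in present genes from 32.6 to 60.5. The last was 47.8 at a limit of mean plus 3 SD (exact p = 0.0397), 60.5 without control 40 (exact p = 0.0159) and 60.3 without BDS 11 (exact p = 0.0317), and the housekeeping signal passed without control 40 (exact p = 0.0238). The cause was not tested.

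Of 68 present named genes given here, 40 kept their direction in all 34 settings. The other 28 turned as follows, as log2 fold changes, and the cause was not tested. With positive controls alone: Csf3r 0.57, Itgam 0.60, Tap1 0.10, Tnfrsf17 0.45, Cx3cr1 0.87, Src 0.72, Cd40lg 0.51, Cd81 0.75, Nfil3 0.67, Il1a 0.90, Ccl4 0.49, Ccl24 0.81, Psmd7 0.84, Tgfbr2 0.85, Ccl3 0.37, Klrc2 1.101, Klrk1 1.13, Cd9 1.23, Pecam1 0.53, Cd34 0.51, Mbp 1.03, Tnf 0.74. With depth as a covariate: C2 -0.099, Psmd7 0.10, Cul9 -0.22, Tcf7 -0.12, Prf1 -0.26, Klrc2 0.18, Cd9 0.18, Mbp 0.042. With TMM: Cul9 -0.073, Ncam1 -0.0032. With median-of-ratios factors in edgeR: Cul9 -0.084, Ncam1 -0.017. With Sdha left out of the scaling: Cul9 -0.097, Ncam1 -0.082, Csf1r -0.024. With limma on the authors' normalized values: Cul9 -0.013, Ncam1 -0.13. With DESeq2 and its own factors: Cul9 -0.082, Ncam1 -0.033. With sample weights in limma: Cul9 -0.091, Cd9 0.021, Mbp 0.0073. With a pseudocount of 20 on those values: Cul9 -0.016, Ncam1 -0.11. With control 52 and 69 left out: Cul9 -0.16, Klrc2 0.059, Cd9 0.15, Mbp 0.082. With control 52 and 69 and BDS 17 left out: Cul9 -0.16, Tcf7 -0.0095, Prf1 -0.17, Klrc2 0.070, Cd9 0.21, Mbp 0.22. With background subtracted in limma: Klrc2 0.81, Klrk1 0.72, Mbp 0.082. With Gapdh left out: Klrk1 0.010. With Polr1b left out: Klrk1 0.020. Tap1, Cd40lg, Klrc2 and Ncam1 were above the limit in 4 lanes only, so their signs are those of values near background.

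Lists turned as follows, as mean differences from other genes, and the cause was not tested. With background subtracted in limma: microglia identity and homeostasis -0.20, complement components and receptors 0.013, inflammatory cytokines and inflammasome 0.13, NF-kB pathway -0.065, cytokine receptor JAK-STAT signalling -0.018, T cells 0.11. With genes above the limit in all 10 lanes: interferon response -0.011, MHC class I presentation 0.071. With no filter: MHC class I presentation 0.044, Fc receptors, scavenging and phagocytosis 0.12, TGF-beta signalling 0.12, immediate early and stimulus response genes 0.072. With a pseudocount of 20: T cells 0.0054. Fry tests a list against no change, so the values set beside it are plain limma mean log2 fold changes, measured from 0 and not from other genes. Those that differed in sign from the planned fit were complement components and receptors 0.041, Fc receptors, scavenging and phagocytosis 0.029, TGF-beta signalling 0.028, T cells 0.038. They are not fry's own statistic. Fry's own direction was down for the complement and TGF-beta lists and up for the phagocytosis and T cell lists. Over left-out pups the ranges of results that turned were Cd9 -0.32 to 0.015, Cul9 -0.11 to 0.15, Klrk1 -0.14 to 0.00066, Mbp -0.27 to 0.053, Ncam1 -0.081 to 0.43, NF-kB pathway -0.040 to 0.052, T cells -0.22 to 0.045, microglia identity and homeostasis -0.016 to 0.047.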

Other observations

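No new test was added here, and the genes below were chosen after the result was seen. With lane depth as a covariate, the smallest p went to Pecam1, an endothelial and leukocyte adhesion gene (log2 fold change -0.85 ± 0.24, SE, n = 5 per group), Tlr9 (-0.58 ± 0.18), the cholesterol transporter Npc1 (-0.69 ± 0.21), the DNA damage kinase Atm (0.94 ± 0.29), Itgam (-0.65 ± 0.21), the Src-family kinase Fyn (0.93 ± 0.31) and Ccl4 (-0.90 ± 0.31), each with an edgeR adjusted p of 0.369. Of the 36 genes at an unadjusted p under 0.05 in that fit, 26 were higher and 10 lower, and 23 were also among the 80 of the fit without it, all 23 in the same direction. Fyn, Lcp2, Ncf4 and Casp8 on the higher side and Itgam on the lower changed little in size between both fits.

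Across the 283 genes, the log2 fold change of BDS over control followed each gene's slope on depth within groups (Pearson r = 0.62; 0.52 from control lanes only and 0.60 from BDS lanes only). Control 40, the deepest control lane, resembled BDS lanes more than its own group (mean r 0.982 against 0.951). Control 18 did so slightly (0.968 against 0.965). The means with control lanes include control 52, the lane least like the others (mean r 0.920 with control lanes). Genes with a mean raw count under 30 had a median log2 fold change of -0.39 (21 genes), those from 300 to 1000 one of 0.26 (72 genes) and those over 1000 one of 0.10 (87 genes). The authors' limit of 23 normalized counts equals 2.72 raw counts in control 52 and 38.6 in BDS 17, so a probe at background can count as present in a shallow lane.

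One hypothesis left for new data is that Itgam is lower in BDS microglia whatever the depth, which might hold since it stayed at -0.65 with depth as a covariate. Lanes of equal RNA signal, or depth balanced between groups, would test it.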
